A study of Mus musculus with 12 samples.

How the data were processed

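RNA was measured by sequencing in the livers of 12 mice, all fasted for 16 h. Per the labels, 5 carried Ube4a alleles flanked by loxP sites (flox) and 7 carried the same alleles with Cre recombinase driven by the Albumin promoter, which removes Ube4a in hepatocytes (LKO). Total RNA was isolated with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols.

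The authors deposited a table of whole-number counts per gene, used here as deposited, with 41708 genes and 1 column per liver. Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the build GRCm39. The gene identifiers and coordinates in the table are those of the C57BL/6NJ strain annotation for 41096 genes, and chromosome 1 reaches position 208807027. Coordinates are therefore given as in the table, and the genome annotation at hand, of another build, was not used. A further 612 loci have no symbol and held 1.36% to 1.95% of the counts. The strand setting of the counting, the read length and the handling of reads shared between similar genes are not given in the sources used here, so genes of families with near-identical members carry that uncertainty. The table of FPKM values, also deposited by the authors, was checked to be the count divided by gene length and by 1 effective size per library, and was used on the scale log2(FPKM + 0.1) and log2(FPKM + 1) as an alternative only.

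Library totals ran from 13399874 to 16525053 counts, and no pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 8.47 to 86.5). The labels list separate mice, and no litter, cage or batch is given. Y-linked genes are not analysed here. Xist reached at most 0.448 CPM in any liver, so the covariate for sex was not fitted.

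Genes were filtered with filterByExpr, which left 12615, and libraries were scaled by TMM. The groups were compared with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are LKO over flox, and CPM values use the scaled library sizes unless stated. Ube4a was also compared by a two-sided exact permutation test over the 792 splits of the livers. Before the data were examined, the design, the alternatives, 37 gene lists with 656 entries and the rule for genes named in the text were fixed. Of the entries, 599 were in the table and 524 were tested, and 32 lists had at least 3 tested members. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with the inter-gene correlation preset at 0.01, adjusted over the 32 lists. The same test with a correlation estimated per list and fry were run beside it. Calculations were run in R 4.3.3.

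The rule named Ube4a and then genes past the threshold by size of change. With fewer than 5 others past it, it took the 10 protein-coding genes with the smallest p and a mean of at least 1 CPM, and the 2 members with the smallest p of each list described, as values and not as changes. Of the list members that the rule names, 2 are not reported here.

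The code was tested on simulated data made from these libraries for the comparison of LKO with flox. Of 12484 simulated genes tested, 200 had been changed. The test recovered 38.7% of those changed 1.5-fold, 74.6% of those changed 2-fold and 82.1% of those changed 3-fold, and 5.71% of its calls were false. In simulated lists of 20 genes, 4 of 4 lists shifted 1.5-fold were recovered and 0 of 16 others were called. Both simulations drew genes independently and set no library apart, so they do not show the rate of false list calls in these livers. Among 100 splits of the real livers, the real one included, at least 15 lists passed in 14. The simulated shift was also larger than the mean change of most lists that passed. In the real data the 95% confidence interval of a fold change reached a median of 0.29 on the log2 scale to either side over all genes tested, and of 0.22 for the 7527 genes above 10 CPM.

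The alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma voom with quality weights, non-robust dispersion, the FPKM scale, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and leaving out each liver in turn. The fits without flox replicates 4 and 5 were added after the data had been seen. They kept only flox replicates 1 to 3, so a call can be lost in them through fewer livers alone. Counts of calls were also taken over 100 of the 792 splits of the livers, drawn with a fixed seed.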

Results

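Liver RNA was sequenced from 5 flox mice and 7 mice with hepatocyte knockout of Ube4a (LKO) after a fast of 16 h, to ask how loss of Ube4a changes gene expression in the fasted liver. Ube4a encodes a ubiquitin chain elongation factor. The libraries held 13399874 to 16525053 counts, and albumin mRNA (Alb) took 5.72% to 8.15% of them.

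Ube4a fell in every LKO liver. The gene (MGP_C57BL6NJ_G0035216) lies on chromosome 9 from 44737000 to 44780476 on the minus strand, in the coordinates of the C57BL/6NJ annotation of the table. Its level was 134 ± 11.6 CPM (SD, n = 5) in flox livers and 26.6 ± 3.45 CPM (SD, n = 7) in LKO livers, 19.8% of the flox mean. The flox livers ranged from 120 to 152 CPM, on 1780 to 2232 counts, and the LKO livers from 23.2 to 34.0 CPM, on 352 to 500 counts. All 12 libraries thus had the Ube4a level that their label gives. The log2 fold change was -2.33 (standard error 0.09, 95% confidence interval -2.53 to -2.14), with an adjusted p of 3.44e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The two-sided exact permutation p was 0.00253.

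**Figure D1:**
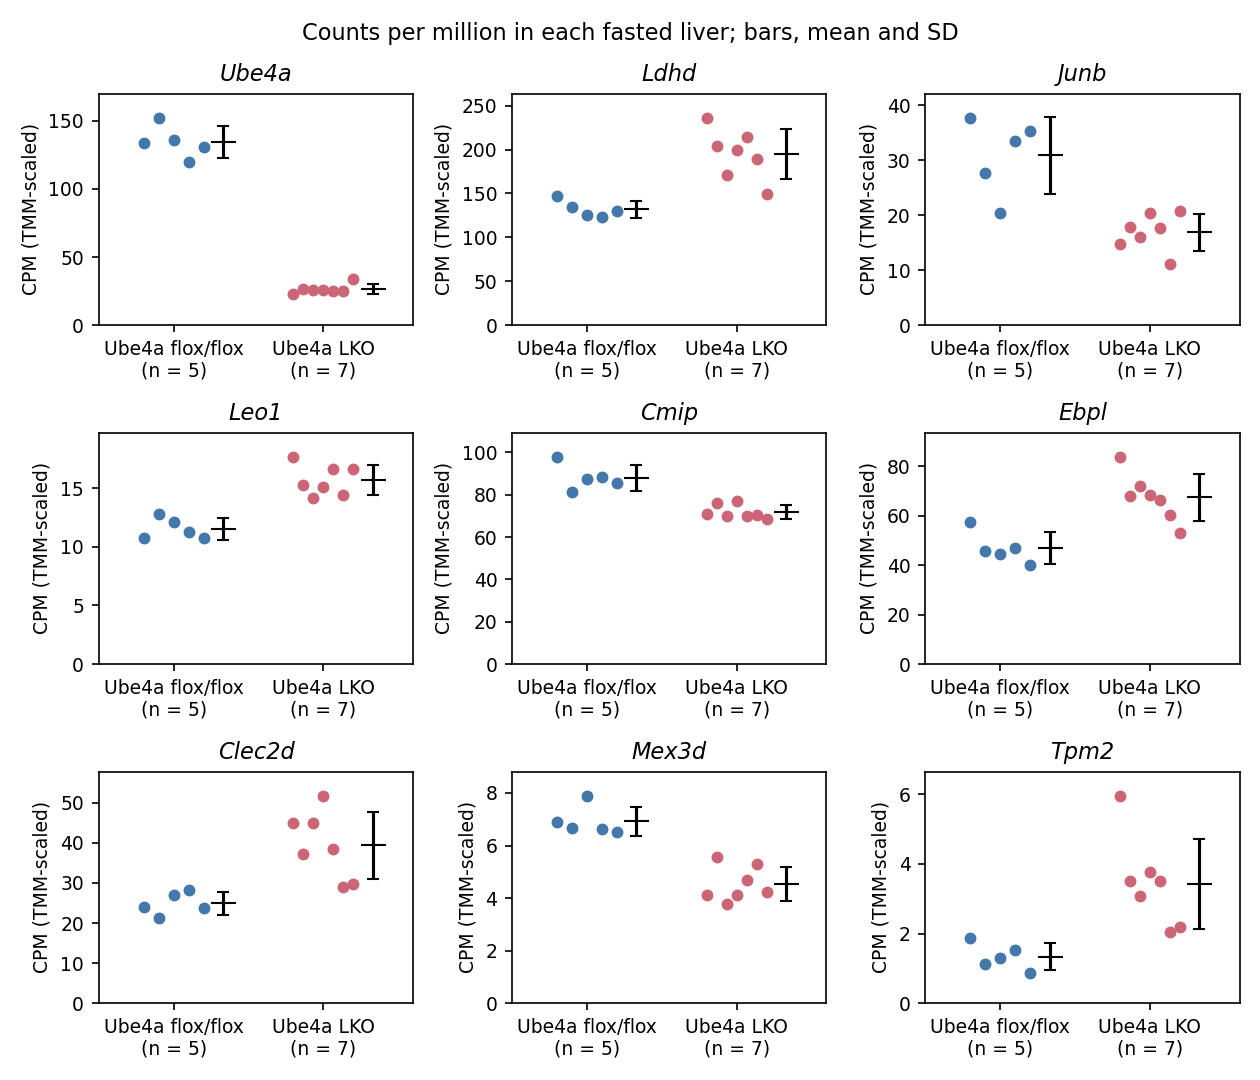
CPM on TMM-scaled library sizes (y axis) for Ube4a and the 8 genes next in order of p by the naming rule, in flox livers (blue) and LKO livers (red). Each point is 1 liver, bars give mean and SD, and every axis starts at 0; Ube4a lies between 23.2 and 34.0 CPM in LKO livers and between 120 and 152 CPM in flox livers.

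Beyond Ube4a, no gene passed the threshold in edgeR's test. Of 12615 genes tested with edgeR, 1 passed, 0 higher and 1 lower in LKO livers, and the second smallest adjusted p was 0.425. At an unadjusted p under 0.05 there were 964 genes, 440 higher and 524 lower, where 630.75 would be expected if no gene differed and genes were independent. Without flox replicates 4 and 5, and so with fewer flox livers, there were 675 of 12811. DESeq2 called 27 genes, 11 higher and 16 lower. Of those 27, 5 were under 1 CPM in every library except flox replicates 4 and 5, and without these libraries DESeq2 called 4 genes, 2 of them shared with the 27. The shared genes were Ube4a and a locus without a symbol (DESeq2 log2 fold change -0.42, adjusted p = 0.0322, and 0.0431 without the pair). That locus had an adjusted p of 0.495 in edgeR with all livers. Without LKO replicate 7, edgeR called 2 genes, the second being Ldhd (log2 fold change 0.61, adjusted p = 0.0426).

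The smallest p-values after Ube4a belonged to genes of several functions, given here as values. Ldhd, a mitochondrial D-lactate dehydrogenase, measured 132 ± 9.77 CPM in flox and 195 ± 28.2 CPM in LKO livers (log2 fold change 0.56, standard error 0.10). Junb, a subunit of the AP-1 transcription factor, measured 30.9 ± 6.95 and 16.9 ± 3.36 CPM (-0.87, standard error 0.17). An unnamed gene with a carboxylesterase domain (MGP_C57BL6NJ_G0034520) measured 186 ± 45.5 and 311 ± 54.8 CPM, and reads shared with related carboxylesterases could not be told apart. Tpm2, a tropomyosin, measured 1.34 ± 0.38 and 3.43 ± 1.30 CPM, and Clec2d, a C-type lectin, 24.9 ± 2.78 and 39.4 ± 8.34 CPM. Log2 fold changes were 0.44 for Leo1, a subunit of the PAF1 transcription elongation complex, 0.52 for Ebpl, 1.09 for Dlgap1, -0.29 for Cmip and -0.61 for Mex3d, an RNA-binding protein. For each of these 10 genes all 7 LKO livers lay on the same side of the flox mean. The genes were chosen for small p in the same livers, so this adds no evidence. Their adjusted p in edgeR was 0.425 to 0.495. DESeq2 placed all 10 under its threshold with all livers (adjusted p from 0.00174 to 0.0314) and 0 of them without flox replicates 4 and 5 (0.248 to 0.942). The fit without the pair held fewer flox livers, so the lost calls do not show that the pair produced them. The log2 fold changes in edgeR without this pair were 0.52 for Ldhd, 0.71 for Clec2d, 1.25 for Tpm2, -0.65 for Mex3d, -0.30 for Cmip, -0.76 for Junb, 0.40 for Leo1, 0.45 for Ebpl, 0.52 for the carboxylesterase gene (0.74 with all livers) and 0.82 for Dlgap1.

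Flox replicates 4 and 5 stood apart from the other 10 livers. The first principal component held 37.3% of the variance and placed them at 45.8 and 64.8, with the next library, LKO replicate 1, at 15.3. Genes of neutrophils were high in these libraries alone: S100a8 measured 61.9 and 99.3 CPM of total counts there and at most 0.22 elsewhere, and Ngp measured 67.2 and 108 CPM there and at most 0.37 elsewhere. The mean of the macrophage list was 1.87 and 2.44 on the log2 scale relative to all libraries, against -1.81 to 0.67 in the other 10. The male-biased list was at -1.30 and -2.29, against -0.38 to 0.89 in the others. Hepatocyte identity genes did not set them apart, at -0.0042 and -0.013. Gene list results are therefore given with and without this pair.

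**Figure D2:**
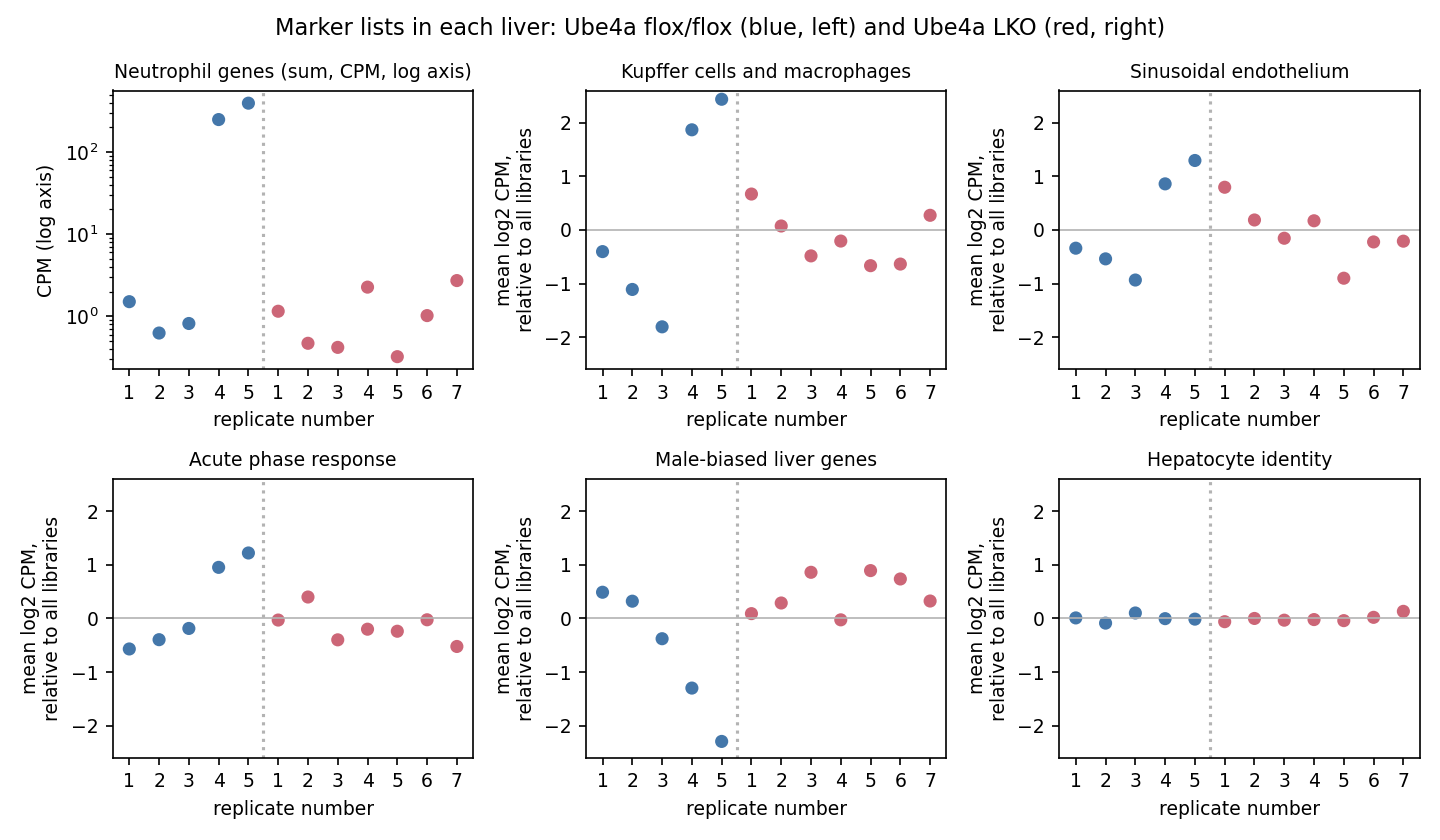
Marker lists in each liver by replicate number (x axis), flox in blue and LKO in red. The first panel sums 10 neutrophil genes in CPM of total counts on a log axis, and the others give the mean log2 CPM of a list relative to all libraries. Flox replicates 4 and 5 reach 248 and 393 CPM of neutrophil genes, and the other livers at most 2.73.

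Among 32 gene lists fixed in advance, 15 passed camera with a preset correlation. None passed with a correlation estimated per list (0 lists, adjusted p = 0.195 to 0.811 with an estimated correlation for the 15). By fry 1 list passed for genes moving in one direction and 0 for either direction. No list member passed over all genes tested, so members are given as values. Without flox replicates 4 and 5, a choice made after seeing the data, 6 of the 15 kept their direction and passed, 5 kept it and did not pass, and 4 turned, 3 of them past the threshold. With fewer flox livers in that fit, a lost call alone need not come from the pair.

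**Figure D3:**
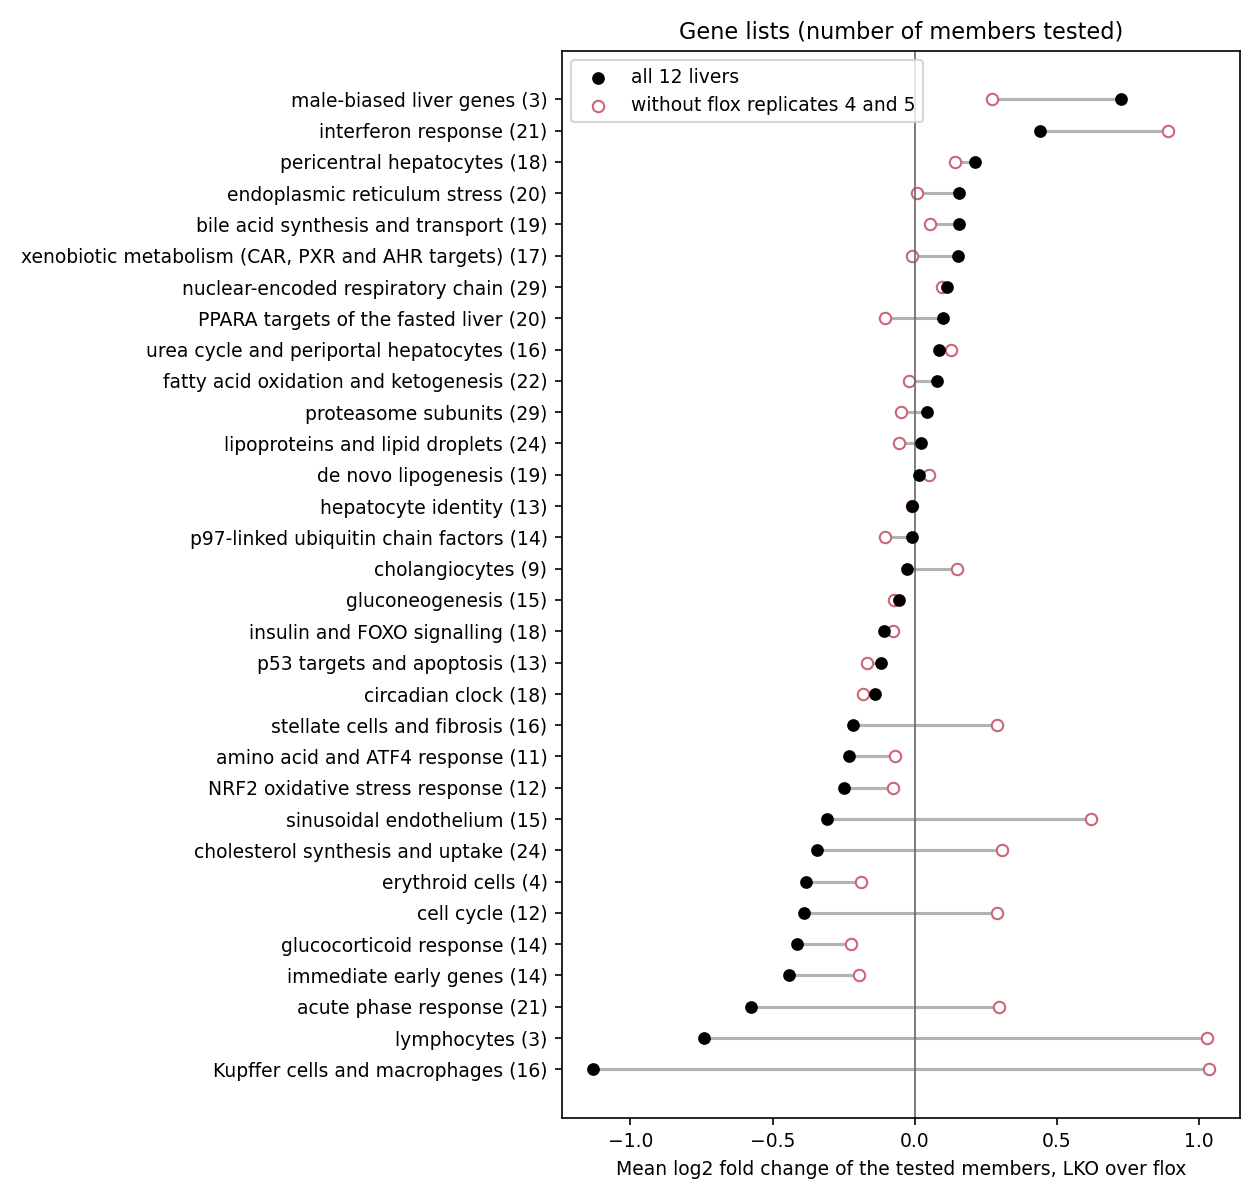
Mean log2 fold change of LKO over flox (x axis) over the tested members of each list (y axis, number of members in brackets), with all 12 livers (filled) and without flox replicates 4 and 5 (open). The macrophage list lies at -1.13 with all livers and at 1.04 without the pair.

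Genes of the ubiquitin and protein quality systems showed small differences. The 14 partners of the p97 segregase and related chain factors, which include the paralog Ube4b, had a mean log2 fold change of -0.01 (adjusted p = 0.99997 by camera), with 0 past the threshold. Ube4b measured 99.5 ± 15.2 CPM in flox and 89.8 ± 10.2 CPM in LKO livers, and Nploc4 190 ± 22.9 and 175 ± 12.9 CPM. Proteasome subunits passed upward with a mean of 0.04 over 29 members, 22 positive and 7 negative (adjusted p = 0.0282, and adjusted p = 0.811 with an estimated correlation). Psma4 measured 87.8 ± 8.98 and 101 ± 5.17 CPM, and Psmb1 147 ± 14.3 and 161 ± 7.48 CPM. The proteasome means were lowest in flox replicates 4 and 5, -0.15 and -0.20, and without them both lists pointed down, at -0.11 and -0.05 (adjusted p = 0.00408 and 0.0405, and adjusted p = 0.254 and 0.683 with an estimated correlation). Endoplasmic reticulum stress genes passed upward with 17 of 20 members positive and a mean of 0.16 (adjusted p = 0.00218, and adjusted p = 0.768 with an estimated correlation). The chaperone Hspa5 measured 624.7 ± 147 and 815 ± 198 CPM, and the translocon subunit Sec61b 5.14 ± 0.37 and 6.91 ± 0.78 CPM. This list was lowest in flox replicates 4 and 5, at -0.30 and -0.42, and its mean without them was 0.01 (adjusted p = 0.947). Leaving out 1 liver ended the proteasome call for flox replicates 1, 4 and 5 and LKO replicates 3, 6 and 7 (adjusted p = 0.0608 to 0.854), as did total counts and 1 surrogate variable (0.0646 and 0.542), and the stress call for flox replicate 5 and LKO replicate 6 (0.0788 and 0.0560). The proteasome mean was 0.011 without flox replicate 4 alone and -0.0030 without flox replicate 5 alone, and the stress mean 0.082 without flox replicate 5 and 0.078 without LKO replicate 6.

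Genes of the amino acid and ATF4 response passed downward, with 9 of 11 members negative and a mean log2 fold change of -0.23 (adjusted p = 0.0345 by camera, and adjusted p = 0.195 with an estimated correlation). This was the list that passed fry in one direction (adjusted p = 0.0190). Ddit4, an inhibitor of mTORC1, measured 36.6 ± 24.3 CPM in flox and 20.04 ± 6.03 CPM in LKO livers, and Ppp1r15a, a regulatory subunit of the eIF2α phosphatase, 12.2 ± 1.31 and 10.2 ± 1.92 CPM. The highest means were those of flox replicates 4 and 5, 0.30 and 0.36. Without them the list passed downward with a median of -0.27 and a mean of -0.07 (adjusted p = 0.0439, and adjusted p = 0.254 with an estimated correlation), and Ddit4 was at 0.03. The call with all livers ended without flox replicate 2 or LKO replicate 1, 6 or 7 (adjusted p = 0.0506 to 0.0869). It also ended with total counts (0.0646), no low-count filter (0.0538), DESeq2 (0.0570) and voom with quality weights (0.0639).

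Genes of the fasting response did not move as 1 group. Gluconeogenic genes had a mean of -0.06 (adjusted p = 0.254), which ran from -0.11 to -0.0050 over the livers left out in turn. Pck1, the rate-limiting cytosolic enzyme, measured 4973 ± 806 CPM in flox and 4261 ± 1052 CPM in LKO livers, with Gk at 303 ± 23.2 and 273 ± 44.9 CPM. Fatty acid oxidation and ketogenesis passed upward with 16 of 22 members positive and a mean of 0.08 (adjusted p = 0.0384, and adjusted p = 0.811 with an estimated correlation). Acadm measured 764 ± 95.3 and 848 ± 63.7 CPM and Acaa2 1365 ± 112 and 1481 ± 59.6 CPM. Its lowest means were those of flox replicates 4 and 5, -0.19 and -0.25, and without them it was at -0.02 (adjusted p = 0.428). PPARA targets had a mean of 0.10 (adjusted p = 0.110), with Cyp4a32 at 246 ± 75.7 and 319 ± 60.9 CPM and Acsl1 at 2665 ± 1080 and 3682 ± 613 CPM. Log2 fold changes were 0.37 for Cyp4a32 and 0.47 for Acsl1, and 0.21 and 0.14 without flox replicates 4 and 5. The PPARA list was at -0.34 and -0.50 in the pair and at -0.11 without it (adjusted p = 0.128). Leaving out 1 liver moved the PPARA mean between 0.0041 and 0.23, and it passed upward without flox replicate 1 or 2 or LKO replicate 4 (adjusted p = 0.00774, 0.0131 and 0.00250) and with voom quality weights (0.00259). Insulin and FOXO signalling passed downward with 14 of 18 members negative and a mean of -0.11 (adjusted p = 0.0426, and adjusted p = 0.195 with an estimated correlation), and without the pair was at -0.08 (adjusted p = 0.0681). Akt1 measured 67.9 ± 7.73 and 58.3 ± 3.99 CPM, and Igfbp1, a secreted protein that insulin represses, 247 ± 72.2 and 149 ± 63.8 CPM. The oxidation call ended without flox replicate 3, 4 or 5 or any LKO replicate except 4 (adjusted p = 0.0607 to 0.418) and with total counts or 1 surrogate variable (0.0646 and 0.255), and the insulin call ended without flox replicate 2, 3 or 4 or LKO replicate 1, 3, 6 or 7 (adjusted p = 0.0505 to 0.147) and with total counts, no low-count filter or DESeq2 (0.0646, 0.0721 and 0.0570). The oxidation mean was 0.040 without flox replicate 4 alone and 0.030 without flox replicate 5 alone.

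Bile acid and cholesterol genes passed in opposite directions with all 12 livers, but not without flox replicates 4 and 5. Bile acid synthesis and transport passed upward with 16 of 19 members positive and a mean of 0.16 (adjusted p = 0.000721, and adjusted p = 0.393 with an estimated correlation). The basolateral transporter Abcc3 measured 378 ± 45.5 and 485 ± 60.8 CPM, and Baat, which conjugates bile acids, 241 ± 20.9 and 286 ± 29.99 CPM. The list was at -0.19 and -0.38 in flox replicates 4 and 5 and had a mean of 0.05 without them (adjusted p = 0.428) and of 0.096 without replicate 5 alone. Cholesterol synthesis and uptake passed downward with 21 of 24 members negative and a mean of -0.34 (adjusted p = 0.0308, and adjusted p = 0.811 with an estimated correlation). Lss, lanosterol synthase, measured 45.2 ± 22.4 CPM in flox and 30.2 ± 6.81 CPM in LKO livers (log2 fold change -0.58, and 0.046 without flox replicates 4 and 5). The highest livers were flox replicates 4 and 5, at 0.69 and 1.05, and without them the list passed upward with a mean of 0.31 (adjusted p = 0.00732, and adjusted p = 0.673 with an estimated correlation). The cholesterol call with all livers also ended without flox replicate 1, 4 or 5 or LKO replicate 1, 2, 6 or 7 (adjusted p = 0.0505 to 0.970) and with total counts (0.0646), and with 1 surrogate variable the mean was 0.02 (0.503). Flox replicate 5 alone moved the cholesterol mean most, to -0.066 without it, while the mean was -0.24 without flox replicate 4, -0.41 without flox replicate 1 and -0.39 with total counts. De novo lipogenesis had a mean of 0.02 and a median of -0.04, tested downward (adjusted p = 0.563), with Fads2 at 594 ± 77.0 and 517 ± 42.6 CPM and Acacb at 182 ± 25.9 and 143 ± 34.2 CPM. Lipoprotein and lipid droplet genes had a mean of 0.02 (adjusted p = 0.464), with Apoc3 at 940 ± 64.9 and 1112 ± 96.7 CPM and Lipe at 18.2 ± 2.33 and 15.1 ± 1.58 CPM.

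Immediate early, glucocorticoid and clock genes passed downward with and without flox replicates 4 and 5, and the clock list lost its call under several other settings. Immediate early genes, which respond within minutes to stimuli and to tissue handling, passed with 11 of 14 members negative and a mean of -0.44 (adjusted p = 7.25e-05, and adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone, 3 members passed and over all genes 0. Egr1 measured 13.9 ± 1.95 and 7.69 ± 3.24 CPM, beside Junb above. Glucocorticoid response genes passed with 13 of 14 members negative and a mean of -0.41 (adjusted p = 0.00299, and adjusted p = 0.195 with an estimated correlation). Mt2, a metallothionein, measured 177 ± 161 and 45.3 ± 28.6 CPM (log2 fold change -1.96, and -0.47 without flox replicates 4 and 5, which held 297 and 398 CPM), and the phosphatase Dusp1 51.2 ± 11.1 and 39.2 ± 5.25 CPM. Circadian clock genes passed with 12 of 18 members negative and a mean of -0.14 (adjusted p = 0.0426, and adjusted p = 0.546 with an estimated correlation). The clock output gene Dbp measured 17.4 ± 5.996 and 8.70 ± 4.49 CPM, and Bhlhe40 74.4 ± 7.94 and 61.8 ± 8.01 CPM. Flox replicates 4 and 5 were highest for immediate early genes, 0.39 and 0.46, and for glucocorticoid genes, 0.38 and 0.41, but not for the clock, 0.06 and -0.02. Without them the means were -0.20, -0.22 and -0.18 (adjusted p = 0.00238, 0.00599 and 0.00408, and adjusted p = 0.320, 0.297 and 0.254 with an estimated correlation). The groups overlapped in each list. For immediate early genes LKO replicates 5 and 7, at 0.029 and 0.16, exceeded flox replicate 2 (0.024). For glucocorticoid genes LKO replicates 2 and 7, at 0.16 and 0.051, exceeded flox replicate 1 (-0.019). For clock genes LKO replicates 4 and 7, at 0.21 and 0.033, exceeded flox replicate 5 (-0.018). In each list the other LKO livers lay below every flox liver. The glucocorticoid list shares Dusp1 with the immediate early list and Per1 with the clock list. Leaving out any single liver kept the immediate early and glucocorticoid calls, while the clock call ended without flox replicate 1, 2 or 3 or LKO replicate 1, 2, 3, 5, 6 or 7 (adjusted p = 0.0540 to 0.190). It also ended with total counts (0.0646), no low-count filter (0.0744), DESeq2 (0.0702) and voom with quality weights (0.0593).

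Acute phase genes passed downward with 18 of 21 members negative and a mean of -0.57 (adjusted p = 0.0104, and adjusted p = 0.811 with an estimated correlation). Lcn2 measured 102 ± 135 and 11.6 ± 6.41 CPM, and Socs3 14.8 ± 4.41 and 9.29 ± 2.48 CPM. That list stood at 0.95 and 1.22 in flox replicates 4 and 5, and without them the list passed upward with a mean of 0.30 (adjusted p = 0.00468, and adjusted p = 0.471 with an estimated correlation), with Lcn2 at 0.74. The acute phase call ended without flox replicate 4 alone (mean -0.44, adjusted p = 0.272), flox replicate 5 alone (mean -0.30, 0.725) or LKO replicate 3 or 7 (0.0532 and 0.0939). With 1 surrogate variable the mean was -0.08 (0.282). Interferon response genes passed upward with 19 of 21 members positive and a mean of 0.44 (adjusted p = 0.0252, and adjusted p = 0.811 with an estimated correlation). Isg15 measured 1.68 ± 0.54 and 3.77 ± 2.80 CPM, and Ifit1 2.52 ± 1.18 and 5.31 ± 4.30 CPM. LKO replicate 1 had the highest interferon mean, 1.58, and without it the list was at 0.03 (adjusted p = 0.481). Outside flox replicates 4 and 5, LKO replicate 1 was also highest for macrophage (0.67), endothelial (0.80) and stellate (0.48) genes. The pair of flox livers was at 0.18 and 0.50, and without it the list was at 0.89 (adjusted p = 2.36e-05, and adjusted p = 0.471 with an estimated correlation), where macrophage and endothelial genes were at 1.04 and 0.62. The interferon call ended too without flox replicate 1, 2 or 3 or LKO replicate 5 (adjusted p = 0.0511 to 0.171), and with voom quality weights the mean was -0.040 (0.932).

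Respiratory chain genes passed upward with and without flox replicates 4 and 5, and pericentral genes with all livers but not without this pair. Leaving out any single liver kept both calls, with means of 0.082 to 0.14 and of 0.15 to 0.26. Nuclear-encoded respiratory chain genes passed with 25 of 29 members positive and a mean of 0.11 (adjusted p = 7.25e-05, and adjusted p = 0.546 with an estimated correlation). Adjusted over the list alone, 4 members passed and over all genes 0. Ndufb3, of complex I, measured 23.5 ± 1.41 and 29.6 ± 2.87 CPM, and Cox7c, of cytochrome c oxidase, 12.2 ± 1.35 and 16.9 ± 2.65 CPM. Flox replicates 4 and 5, at -0.09 each, lay among the other flox livers, and without them the mean was 0.09 (adjusted p = 0.0107, and adjusted p = 0.667 with an estimated correlation). The LKO livers did not lie together. LKO replicates 1, 3 and 4 were at 0.11, 0.12 and 0.16, above every flox liver. LKO replicates 2, 5, 6 and 7 were at 0.0037, -0.068, -0.041 and 0.038, below flox replicate 2 (0.076) but above the other flox livers. Pericentral hepatocyte genes passed with 16 of 18 members positive and a mean of 0.21 (adjusted p = 0.00299, and adjusted p = 0.195 with an estimated correlation), with Lect2 at 32.6 ± 5.18 and 50.0 ± 13.44 CPM and Rgn at 112 ± 58.3 and 221 ± 72.9 CPM. The pair was at -0.16 and -0.37, and without it the mean was 0.14 and the median 0.010, with 10 of 18 positive (adjusted p = 0.131). Urea cycle and periportal genes had a mean of 0.09 (adjusted p = 0.297; mean 0.018 to 0.11 over the livers left out in turn). Cyp2f2, at 388 ± 66.1 and 590 ± 129 CPM, and Otc, at 190 ± 35.1 and 271 ± 50.6 CPM, were the 2 members that passed adjusted over the list alone, with 0 over all genes. The 3 male-biased genes tested passed upward with a mean of 0.73 (adjusted p = 0.0142, and adjusted p = 0.345 with an estimated correlation), with Elovl3 at 94.7 ± 98.6 and 214 ± 101 CPM and Cyp7b1 at 158 ± 43.9 and 201 ± 58.0 CPM. Their mean was 0.27 without flox replicates 4 and 5 (adjusted p = 0.428), and the call ended without flox replicate 5 alone (adjusted p = 0.0616).

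Other lists did not pass with all livers. Xenobiotic metabolism had a mean of 0.15 (adjusted p = 0.170; mean 0.33 and adjusted p = 0.0101 without flox replicate 1), with Ces2a at 136 ± 29.2 and 205 ± 45.3 CPM and Aldh1a1 at 1018 ± 364 and 1513 ± 350 CPM. NRF2 targets had a mean of -0.25 (adjusted p = 0.384). Nqo1, a quinone reductase, at 9.08 ± 1.71 and 14.0 ± 2.84 CPM, was the 1 NRF2 member that passed adjusted over the list alone, with 0 over all genes, while Hmox1 measured 22.04 ± 14.2 and 10.98 ± 4.08 CPM (log2 fold change -1.01, and -0.22 without flox replicates 4 and 5). P53 targets had a mean of -0.12 (adjusted p = 0.410), with Btg2 at 23.9 ± 14.0 and 14.1 ± 5.21 CPM and Sesn2 at 21.6 ± 4.68 and 18.0 ± 3.04 CPM. Log2 fold changes were -0.77 for Btg2 and -0.26 for Sesn2, and -0.11 and -0.41 without flox replicates 4 and 5. Hepatocyte identity genes had a mean of -0.01 and a median of 0.06 (adjusted p = 0.995), with Hnf4a at 1341 ± 92.4 and 1208 ± 136 CPM and Ahsg at 8864 ± 1290 and 7769 ± 857 CPM.

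Macrophage, endothelial, stellate and cell cycle genes were highest in flox replicates 4 and 5. All 16 macrophage genes tested had negative fold changes, with a mean of -1.13 (adjusted p = 0.192), and Cd163 measured 49.6 ± 57.7 CPM in flox and 15.2 ± 5.73 CPM in LKO livers, and Ccr2 2.25 ± 2.595 and 0.66 ± 0.39 CPM. Sinusoidal endothelium had a mean of -0.31 (adjusted p = 0.464), with Lyve1 at 13.8 ± 11.4 and 7.86 ± 3.53 CPM and Cdh5 at 19.8 ± 18.4 and 12.4 ± 6.13 CPM. Stellate cells had a mean of -0.22 (adjusted p = 0.254), with Vim at 31.2 ± 18.3 and 19.9 ± 3.50 CPM and Pdgfrb at 6.60 ± 2.06 and 5.04 ± 1.43 CPM. Cell cycle genes had a mean of -0.39 (adjusted p = 0.254), with Mcm6 at 3.94 ± 3.36 and 2.16 ± 0.46 CPM and Mcm5 at 1.72 ± 2.13 and 0.63 ± 0.18 CPM. Without the pair these 4 lists passed upward, with means of 1.04, 0.62, 0.29 and 0.29 (adjusted p = 2.11e-11, 1.99e-06, 0.00195 and 0.0283), and none did with a correlation estimated per list (adjusted p = 0.254, 0.419, 0.471 and 0.254 with an estimated correlation). Leaving out flox replicate 3 alone, the 4 lists passed downward instead (adjusted p = 0.000571, 0.0196, 0.00161 and 0.0407), as they did with voom quality weights (0.000256, 0.00368, 0.00218 and 0.0316). Those weights did not discount the pair: flox replicate 4 had the highest weight, 2.20, and flox replicate 5 had 0.94, against 0.60 to 1.77 in the others. Macrophage genes also passed downward without flox replicate 2 (0.0155) and with DESeq2 (1.17e-05), and cell cycle genes with no low-count filter (0.00358). With 1 surrogate variable macrophage and endothelial genes passed upward (means 0.25 and 0.23, adjusted p = 0.0112 and 0.00376). Without flox replicate 5 alone the macrophage, endothelial and stellate means were -0.45, 0.069 and 0.018. The cell cycle mean ran from -0.53 to -0.10 over the livers left out in turn. Lymphocyte genes, 3 of them tested, had a mean of -0.74 although camera's direction was upward (adjusted p = 0.979), and a mean of 1.03 without the pair (adjusted p = 0.00962, and adjusted p = 0.254 with an estimated correlation). Ptprc measured 6.86 ± 7.12 and 3.21 ± 1.15 CPM and Jchain 7.48 ± 1.69 and 10.2 ± 3.89 CPM. Cholangiocyte genes, highest in LKO replicate 3 (0.58), had a mean of -0.03 and a median of 0.10 (adjusted p = 0.979), and erythroid genes, highest in flox replicate 1 (0.84), a mean of -0.38 (adjusted p = 0.583). Among them Cd24a measured 4.57 ± 3.30 and 2.599 ± 0.95 CPM, Spp1 24.7 ± 4.92 and 31.9 ± 8.399 CPM and Alas2 33.8 ± 11.6 and 47.2 ± 14.7 CPM.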

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

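The tests of flox replicates 4 and 5 were chosen only after their position had been seen, and the counts over other splits were planned before.

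In 90 tests for a single liver far from its group, 8 met the criterion and 4.5 would be expected by chance. Ube4a in LKO replicate 7 was 34.0 CPM, 25.3% of the flox mean, with the next LKO liver at 26.8 CPM. Mex3d in flox replicate 3 was 7.87 CPM, with the next flox liver at 6.89 CPM. In LKO replicate 4 the means of fatty acid oxidation and PPARA targets were -0.14 and -0.59, with the next LKO livers at 0.04 and 0.01. In flox replicate 1 the means of insulin signalling and of periportal genes were -0.059 and -0.38, with the next flox livers at 0.07 and 0.01. In flox replicate 2 the respiratory chain mean was 0.076, with the next flox liver at -0.09. In LKO replicate 7 the hepatocyte identity mean was 0.13, with the next LKO liver at 0.02.

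Flox replicates 4 and 5 stood apart from the other 10 livers in neutrophil, macrophage, acute phase and cell cycle genes. For endothelial genes replicate 4 (0.86) lay near LKO replicate 1 (0.80). A swap with LKO livers is argued against by Ube4a, since the lower of the pair, at 120 CPM, was 3.52 times the highest LKO liver, and a difference in depth by the first component after thinning all libraries to the smallest total, where the pair still lay beyond the others by 0.679 of the range of those 10. A candidate explanation is 1 RNA source, such as another tissue or blood cells in whole-tissue RNA with no sort, present in both at 2 amounts: the excess in replicate 4 was 0.631 of that in replicate 5 for 10 neutrophil genes, which reached at most 1.30 CPM elsewhere (Csf3r), 0.646 for macrophage, 0.626 for endothelial (0.252 to 0.685 by the liver taken as baseline), 0.576 for lymphocyte and 0.519 for stellate genes. The largest difference, 0.112 for stellate genes, exceeded the 0.1 set for the test, which by its rule counts against 1 source. Outside that rule, the stellate ratio ran from 0.178 to 0.636 by the liver taken as baseline. The lymphocyte ratio ran from 0.342 to 0.604. Among neutrophil genes Csf3r at 0.843 (95% interval 0.660 to 1.08) and Ly6g at 2.34 (1.03 to 5.81) departed from the neutrophil ratio. The ratio was also 0.661 for acute phase and 0.640 for cholesterol genes, which mark no other cell type. A shared ratio thus does not mark an added source. Acute phase genes, which hepatocytes express, summed to 37301 and 44932 CPM of total counts in the pair and at most 30298 elsewhere. This argues against blood cells or another tissue as their source. For the cell type genes that were high, such a source cannot be told apart from a graded state of both mice. An added source is argued against for the 3 male-biased genes tested, since it dilutes all hepatocyte genes alike. Their mean minus that of hepatocyte identity genes was -1.29 in the higher of the pair, 0.815 below the lowest other liver (SD of the other 10 0.431). Of the 3, Cyp7b1 in flox replicate 4, at 133 CPM, lay beside LKO replicate 1 at 132 CPM. No biological explanation was tested, since the design gives both the genotype and fast of the other flox livers.

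Over 100 splits of the 12 livers, the real one included, 1 gave a p as small as that of Ube4a for any gene (2.72e-13, against 2.86e-06 in the next split), so chance is excluded for Ube4a. It is not excluded for the count of lists. In the real split the counts of genes and of lower genes held Ube4a alone, so they cannot test chance for other genes. At least 1 gene was called in 7 splits (highest other 10) and at least 1 lower gene in 7 (highest other 7). With 0 higher genes in the real split, their count cannot be tested (highest other 3). Genes at p under 0.01 numbered 194 in the real split and 10 to 850 in the others. At least 15 lists passed in 14 splits (highest other 20). Most of these other splits kept flox replicates 4 and 5 in 1 group, as the real split did. The split with 20 lists was among them. More than 1 gene was called in 4 of the 48 other splits that kept flox replicates 4 and 5 in 1 group and in 1 of the 51 that parted them. The split with 10 genes was among the 48, and whether these shares differ was not tested.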

How the results depend on the processing

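The fits without flox replicates 4 and 5 were chosen after seeing the data, and all other alternatives were planned. The cause of a change was not tested except where stated. Ube4a kept its fall in all 26 alternatives (log2 fold change -2.41 to -2.03, largest adjusted p 5.17e-05). The count of genes was 1 except with DESeq2, 27 (11 higher, 16 lower), with DESeq2 without flox replicates 4 and 5, 4 (0 higher, 4 lower), and over the livers left out in turn, 1 to 2 (0 to 1 higher, 1 lower), the 2 without LKO replicate 7. The 10 other named genes passed with DESeq2. The number of lists, 15, was 9 with total counts only, 0 with an estimated correlation, 0 with that and without flox replicates 4 and 5, and 1 and 0 by fry for one and either direction. It ran from 8 to 16 over the livers left out in turn, with 9 without LKO replicate 1, 8 without LKO replicate 6 and 8 without LKO replicate 7, and 5 lists kept their call throughout. Without flox replicates 4 and 5 the mean of p97-linked factors was -0.11 (-0.01 with all livers, where camera's direction was upward at an adjusted p of 0.99997), and list means turned to -0.049 for proteasome, -0.020 for fatty acid oxidation, 0.31 for cholesterol, 0.30 for acute phase, 0.29 for cell cycle, 1.04 for macrophages, 0.29 for stellate cells and 0.62 for endothelium. DESeq2 without them gave -0.11, -0.055, -0.027, 0.31 and 0.23 for the first 5, and 0.95, 0.31 and 0.62 for the last 3. The lymphocyte mean went from -0.74 to 1.03 without them. With 1 surrogate variable macrophages were at 0.25 and endothelium at 0.23 and both passed, the cholesterol and acute phase means went to 0.02 and -0.08 (adjusted p = 0.503 and 0.282) and the proteasome and fatty acid oxidation calls ended, and with voom quality weights the interferon list was at -0.040. A further 38 list means or genes changed sign with no call under either setting. The replicate numbers shared by both groups do not pair the samples: correlations of deviations for numbers 1 to 5 were -0.15, 0.02, 0.10, 0.03 and -0.29. With the number as a replicate block, on 10 livers, the counts were 1 gene (0 higher, 1 lower) and 7 lists (the proteasome, ATF4, fatty acid oxidation, cholesterol, insulin, clock, acute phase and male-biased lists did not pass, adjusted p = 0.0645 to 0.389), Ube4a was at -2.41, and 820 of 12467 genes had an unadjusted p under 0.05. Without flox replicates 4 and 5 this was 675 of 12811. The covariate for sex was not run, since no liver had Xist above 0.448 CPM, and lists were not rerun with non-robust dispersion, which camera does not use. Depth limits genes of few counts. The 95% interval of a log2 fold change reached a median of 0.29 to either side over all genes and 0.22 above 10 CPM. These widths also hold the variation between livers, so they do not measure depth alone.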

Other observations

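The test of strain DNA on chromosome 8 was chosen after the gathering of genes had been seen, as were the genes named next.

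From the 27 genes under the threshold of DESeq2, 5 more were picked by hand and form no tested group. Pecr, a peroxisomal enoyl-CoA reductase, had a DESeq2 log2 fold change of 0.62 (adjusted p = 0.0169, and 0.495 in edgeR). Mbl1, a mannose-binding lectin of the complement system, was at 0.43 (0.0279 and 0.495), and the sulfotransferase Sult5a1 at 1.15 (0.0279 and 0.505). Ulk1, the kinase that starts autophagy, was at -0.31 (0.0215 and 0.495), and Gpc1, a cell-surface heparan sulfate proteoglycan, at -0.99 (0.0167 and 0.505). Without flox replicates 4 and 5 the DESeq2 adjusted p of these genes was 0.567, 0.859, 0.463, 0.848 and 0.194, with log2 fold changes in edgeR of 0.59 for Pecr, 0.39 for Mbl1, 1.16 for Sult5a1, -0.28 for Ulk1 and -1.09 for Gpc1.

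Of the 10 genes named by p after Ube4a, Ldhd, Junb, Cmip and the unnamed carboxylesterase gene lie on chromosome 8. At p under 0.01 there were 20 of 692 tested genes of chromosome 8 (2.89%, against 1.46% of genes elsewhere; one-sided Fisher's exact p = 0.00491, adjusted over chromosomes 0.0491) and 17 of 505 of chromosome 15 (3.37%, p = 0.00204, adjusted 0.0408). Among 100 splits of the livers 12 gave some chromosome a p as small as that of chromosome 8 (smallest other 0.000138), so chance is not excluded. DNA of another strain linked to the Cre transgene, whose insertion site is not given in the sources used here, could gather such genes on 1 chromosome. Without flox replicates 4 and 5 the share on chromosome 8 was 1.14% against 0.776% elsewhere, a ratio of 1.47 (Fisher's exact p = 0.194, adjusted 0.751). Chromosome 15, at 1.96% against 0.748% (Fisher's exact p = 0.00745, adjusted 0.149), and chromosome 1, at 1.55% (p = 0.0198, adjusted 0.198), then had smaller p-values, and with 8 genes of chromosome 8 at p under 0.01 the explanation cannot be told apart from chance.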
